A study of Mus musculus with 6 samples.

How the data were processed

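RNA was measured in 6 samples of mouse T cells, 3 carrying an E47-ER retrovirus and 3 carrying a control bHLH-ER retrovirus, on Affymetrix mouse expression arrays with biotin-labelled total RNA. Per the labels' protocols, CD4+CD25- cells from C57BL/6 lymph nodes were grown on plates coated with anti-CD3 at 2 µg/ml and anti-CD28 at 1 µg/ml. IL-2 at 200 U/ml and TGF-β1 at 5 ng/ml were present for 2 days, and the virus was added on day 1. Transduced cells were sorted as CD4+Thy1.1+ and kept for 6 hours with IL-2, plate-bound antibodies and 1 µM tamoxifen before RNA was taken. Tamoxifen lets proteins fused to the ligand-binding domain of the estrogen receptor (ER) enter the nucleus. What the bHLH-ER control construct contains beyond its name is not given in the sources used here.

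The authors deposited 1 intensity per probe set and array, and RMA is the processing tool named, with no version, per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of a set. The deposited values were on a linear scale, although a log2 scale had been assumed before the data were examined, so log2 was taken first. The median intensity of an array lay between 34.3 and 35.4, and every value was above 0, with 4.26 as the lowest.

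Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation used here, 932 had several and 9211 were not listed there and are unnamed here. Of the named ones, 34754 matched an entry of the RefSeq gene table by Entrez number, and 0 symbols changed through it. The 64 Affymetrix control probe sets were kept out of the gene tests. Each gene was represented by its probe set with the highest mean log2 value over the 6 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No dim gene was removed.

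Groups and replicate numbers came from the sample titles. The comparison of E47 with control used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) over all genes, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The fit had the group as its only term. A fit with the experiment as a block, called the paired fit, was an alternative fixed at the same time. Each of 31 gene lists, holding 606 symbols of which 555 were measured, was tested with camera at a preset correlation of 0.01 between genes. It was repeated with the correlation estimated from the data and with fry. Lists counted members that passed the threshold over all genes, and also members that passed when adjusted over the list alone. The fits, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, and the exceptions are named where they occur.

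Named genes were Tcf3, Esr1, Thy1, Foxp3, Spib, Socs3, Id2 and Id3 in every case. The 12 largest rises and 12 largest falls among genes past the threshold that moved the same way in all 3 pairs were added, passing over genes with only a clone name or number. From each list came up to 4 members past the threshold and up to 2 that did not pass, by lowest p. The rule for the largest rises and falls was also applied to the paired fit, after the unpaired fit had given 1 fall. Other genes are named where a count was 5 or fewer or where experiments were compared, and these were chosen after their values were seen. Spib, Socs3 and Foxp3 are genes the study is known to discuss, so their place in a list is no independent evidence.

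The pairing was checked first. The design text gives 3 independent experiments, each with 1 control and 1 E47 sample, and same-numbered samples shared the age of the mice and the number of mice pooled. Deviations from the group means correlated, across genes, at 0.28, 0.67 and 0.43 for same-numbered arrays, all above the limit of 0.1. Differently numbered arrays of experiments 1 and 3 also correlated, at 0.25 (control 3 with E47 1) and 0.18 (control 1 with E47 3), while those involving 1 array of experiment 2 lay between -0.52 and -0.34. The correlations thus set experiment 2 apart and separate experiments 1 and 3 little, and the pairing rests on the design text and the numbers. The consensus correlation from duplicateCorrelation was 0.32. Genes that differed between experiments were tested in the paired fit with an F test of the block.

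Both fits were tested on simulated data of 18193 genes. Simulated changes of 1 on the log2 scale were recovered in 71% of cases without the block and 80% with it, and changes of 2 in 95% and 94%. There were 1 and 7 false calls, and the list shifted on purpose was the 1 list called in each. The simulated noise was independent between genes, so this does not show how the list test behaves on correlated genes. In the real data, without the block, the estimated correlation within a list ran from -0.15 (construct genes) to 0.90 (cholesterol synthesis). Arrays carry no read depth, and their number, 3 per group, limits the precision.

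Alternatives tried were the fixed and random block, median centring, quantile normalization, cyclic loess, a filter on dim genes, the mean of a gene's probe sets, trend and robust variance, array weights and leaving out each array and each pair. The probe sets with several symbols or none were tested one by one, and only their counts and the largest difference are given. Plots were drawn with matplotlib 3.10.9 from tables handled in pandas 2.3.3 and numpy 2.4.6.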

Results

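The data were 6 arrays of mouse CD4 T cells that had been steered towards a regulatory T cell (Treg) fate with TGF-β1 and IL-2 in culture. E47 is a basic helix-loop-helix (bHLH) transcription factor, a splice product of the Tcf3 gene, that binds DNA at E-box sites and is held back by Id proteins. In 3 samples E47 was carried by a retrovirus as a fusion to the ER domain, and 3 control samples carried a construct named bHLH-ER. The same 6 hours of tamoxifen were given to both groups. The 3 experiments used mice of 7, 8 and 9 weeks, with 3, 3 and 4 mice pooled per sample, and each gave 1 control and 1 E47 sample. Correlations between control and E47 arrays over all genes lay between 0.987 and 0.997.

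The introduced gene was examined first. Tcf3 had log2 levels of 8.91, 8.94 and 8.91 in control replicates 1 to 3 and 8.95, 8.81 and 8.97 in E47 replicates 1 to 3, a log2 fold change of -0.01 (SE 0.08, adjusted p = 0.984). Its 3 probe sets had log2 fold changes of -0.01, 0.28 and 0.02, and none passed the test. Where these probe sets lie relative to the cloned part was not analysed here, and a probe set outside that part checks nothing. Esr1, the mouse gene of the estrogen receptor, had a log2 fold change of 0.21 (SE 0.13, adjusted p = 0.832). Both constructs carry an ER domain, but their sequences are not in the sources used here, so its species is not known. Thy1, whose Thy1.1 form marked the transduced cells for sorting, had log2 levels of 11.94 ± 0.32 in control and 12.77 ± 0.25 in E47 samples (SD, n = 3). It rose in the paired fit (log2 fold change 0.82, SE 0.09, adjusted p = 0.0138), and its adjusted p without the pairing was 0.301. The paired call was lost without pair 2 (adjusted p = 0.0949) and without pair 3 (0.113).

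E47 samples were set against control samples to ask which genes differed between the constructs after 6 hours of tamoxifen in Treg-like cells. No sample lacked tamoxifen, so changes within those hours cannot be told apart from earlier effects of the constructs. Id2 and Id3, which encode inhibitors that pair with E proteins and stop them from binding DNA, rose 6.24-fold and 3.10-fold (adjusted p = 0.00163 and 0.00587). Cxcr5, the receptor for CXCL13 that guides cells to B cell follicles, rose by 4.11 on the log2 scale, from a level of 4.57 ± 0.04 to 8.68 ± 0.07 (SD, n = 3, adjusted p = 1.72e-06). Spib, an Ets family factor of B cells and plasmacytoid dendritic cells, rose 5.36-fold (adjusted p = 0.0169), and Ighm, the µ heavy chain gene, rose 4.13-fold (adjusted p = 0.00584). Foxp3, the lineage factor of Treg cells, had a log2 fold change of -0.20 (SE 0.60, adjusted p = 0.966), with 6.42, 8.16 and 6.29 in control and 6.36, 7.83 and 6.07 in E47 replicates 1 to 3. Its level was lower in E47 in each pair (-0.06, -0.33 and -0.22), and it did not pass in the paired fit (SE 0.09, adjusted p = 0.427).

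In the fit without the pairing 45 of 18193 genes changed, 44 upwards and 1 downwards, and 40 rose at least 2-fold. The paired fit gave 142 upwards and 66 downwards, so falls were less rare there. Among its changes of at least 2-fold, 78 were upwards and 6 downwards, so large falls were few in both fits. Each of the 45 moved the same way in all 3 pairs. Cst6, a cystatin that inhibits cysteine proteases, rose by a log2 fold change of 4.46 (SE 0.43), Gprin2 by 4.35 (SE 0.20) and Tshb, the β chain of thyroid-stimulating hormone, by 4.24 (SE 0.42). Cidea, a lipid droplet protein of brown fat, rose by 3.33 (SE 0.29) and Wnt10a, a secreted Wnt ligand, by 3.08 (SE 0.40). Epcam, an epithelial adhesion molecule, rose by 3.04 (SE 0.40), while its other probe set had a log2 fold change of 0.20. The tetraspanin gene Tspan2 rose by 2.78 (SE 0.36), Ccdc141 by 2.55 (SE 0.19; 1.91 in another of its 6 probe sets and 0.15 to 0.24 in the rest) and Plaur, the urokinase receptor, by 2.54 (SE 0.21). Cxcr4, the receptor for CXCL12, rose by 2.08 (SE 0.17), Il4, the signature cytokine of Th2 cells, by 1.46 (SE 0.12) and Bcl2l11, which encodes the death-promoting protein Bim, by 2.11 (SE 0.28). Control levels of Cxcr5, Gprin2, Tshb, Cidea, Ccdc141 and Cxcr4 lay below the median of all probe sets; detection above background was not tested, so the sizes of these rises are uncertain. The 1 gene that fell without the pairing was Rgs2, a brake on G protein signalling (log2 fold change -0.91, SE 0.12, adjusted p = 0.0455).

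Of the 18 named genes called without the pairing, 9 passed whichever single array was left out, and Cxcr5 and Gprin2 also passed whichever pair was left out. In this unpaired fit the calls of Wnt10a, Epcam, Tspan2, Bcl2l11 and Rgs2 were lost most often. With 1 array left out their adjusted p reached 0.212 (without control replicate 3), 0.228 (without control replicate 1), 0.203 (without E47 replicate 3), 0.221 (without control replicate 1) and 0.246 (without control replicate 3). With a pair left out it reached 0.681, 0.564, 0.635, 0.578 and 0.760. Spib reached 0.102 without control replicate 3, Cst6 0.0893, Tshb 0.0914 and Cidea 0.0580 without control replicate 1. With a pair left out Spib reached 0.491, Cst6 0.304, Tshb 0.338 and Cidea 0.208. In the paired fit Epcam, Tspan2 and Bcl2l11 passed whichever pair was left out (adjusted p = 4.25e-04, 1.90e-04 and 0.00111 with all pairs). Spib was lost there without pair 2 (adjusted p = 0.0808) and without pair 3 (0.140), and Wnt10a and Rgs2 without pair 3 (0.0904 and 0.0707).

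**Figure D1:**
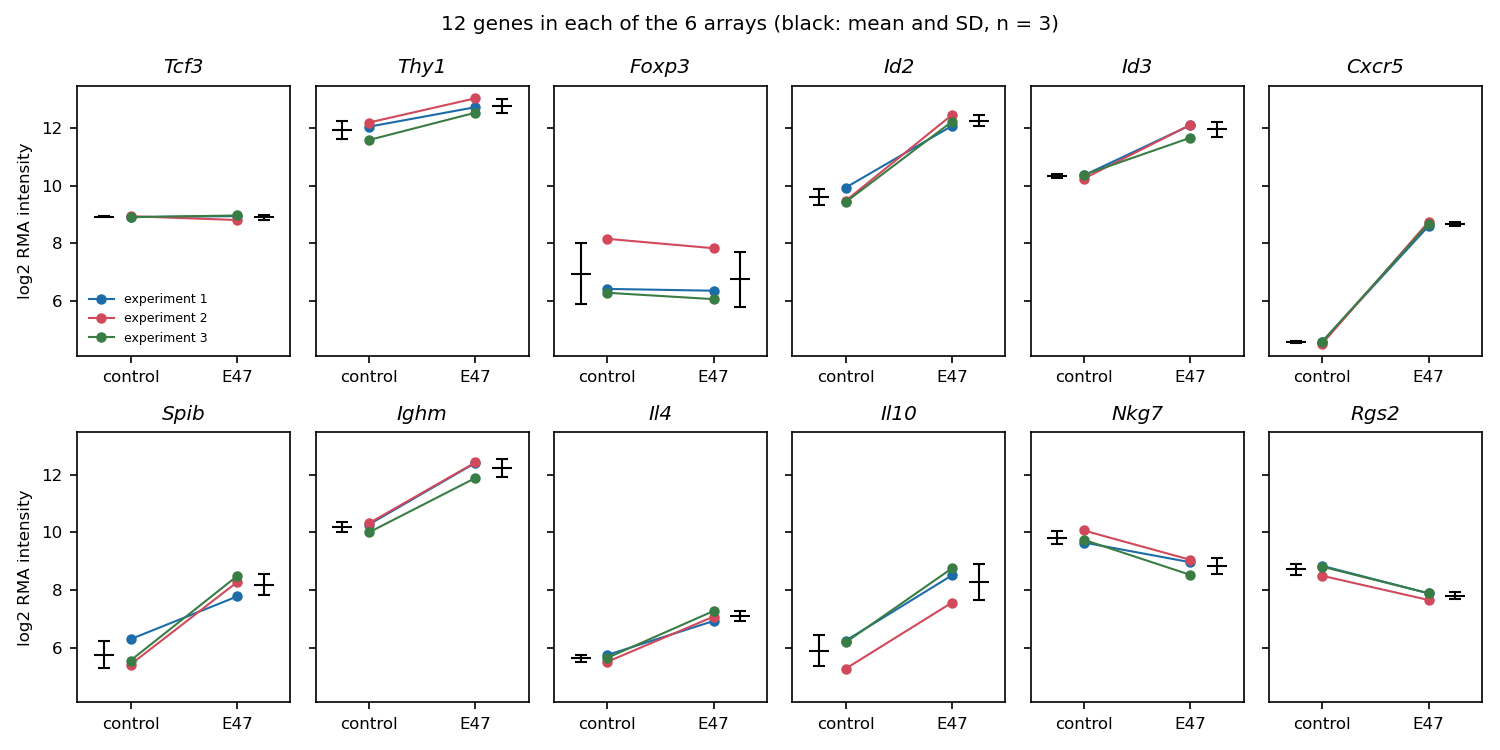
Log2 RMA intensity (vertical axis) of 12 genes in each array, control on the left and E47 on the right of each panel; coloured lines join the samples of 1 experiment and black bars give the mean and SD of 3 arrays. Cxcr5 lay between 8.61 and 8.76 in E47 arrays against 4.52 to 4.59 in control arrays, while Foxp3 differed more between experiments than between groups.

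**Figure D2:**
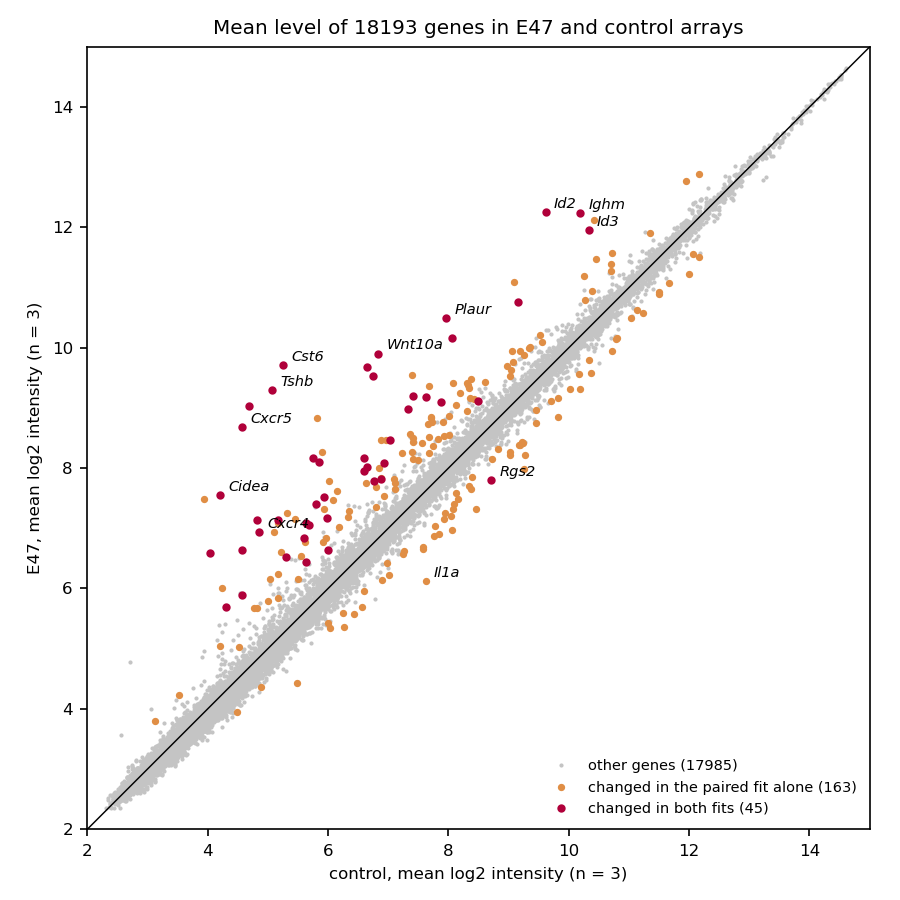
Mean log2 intensity of 18193 genes in control (horizontal axis) and E47 arrays (vertical axis), n = 3 each; the line marks equal levels. The 45 genes that changed in both fits lie above the line except Rgs2, and 163 more changed in the paired fit alone.

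Within the E protein and Id family, 2 of 15 measured members rose, Id2 and Id3, and 4 rose when adjusted over the list alone. In the paired fit Id1 (log2 fold change 1.06, adjusted p = 0.0170) and Mxd1 (1.22, adjusted p = 0.00529), a partner of Max that opposes Myc, rose as well and Tal2 fell (-0.92, adjusted p = 0.00789). Without pair 2 the adjusted p of Id1 was 0.0552 and that of Tal2 0.0645, and without pair 3 these were 0.0814 and 0.0904, and Mxd1 was just above the threshold (0.05001). The list rose in camera (adjusted p = 0.0041, adjusted p = 0.215 with an estimated correlation), with a mean log2 fold change of 0.35 and a median of -0.01. Among 31 lymphoid targets of E proteins 3 rose, Cxcr5, Cxcr4 and Spib, and 4 when adjusted over the list alone. The paired fit added Gfi1, a transcriptional repressor of lymphoid and myeloid cells (1.47, adjusted p = 0.00602), and Socs3, an inhibitor of cytokine signalling (1.06, SE 0.12, adjusted p = 0.0193). Without the pairing the adjusted p of Socs3 was 0.823, and the paired call was lost without pair 2 (0.0644) and without pair 3 (0.145). The 3 Socs3 probe sets had log2 fold changes of 0.58, 1.06 and 0.98. Adjusted over all probe sets in place of genes, none of them passed in the paired fit (adjusted p = 0.503, 0.0668 and 0.148). This list also rose (adjusted p = 2.42e-04, adjusted p = 0.179 with an estimated correlation).

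Of 22 B lineage genes 2 rose, Ighm and Spib, and also 2 when adjusted over the list alone. Pou2af1, a coactivator of octamer-dependent immunoglobulin transcription, fell in the paired fit (-0.64, adjusted p = 0.0322) but in none of the fits with 1 pair left out (adjusted p = 0.0505, 0.223 and 0.124 without pairs 1, 2 and 3), and Cd79a, a chain of the B cell receptor, had a log2 fold change of -0.20 (SE 0.13). The list did not shift (adjusted p = 0.654, median -0.03, mean 0.13). Of the 11 Ighm probe sets the 2 brightest had log2 fold changes of 2.05 and 2.03 and the others lay between -0.25 and 0.04. The mean over its probe sets did not pass (adjusted p = 0.495).

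With the experiment as a block, 208 genes changed, 84 of them by at least 2-fold. All 45 genes were among them. Cdh1, the adhesion molecule E-cadherin, rose in all 3 pairs from a dim control level, a log2 mean of 3.94, to 7.48 (adjusted p = 3.04e-04) and Il10, an anti-inflammatory cytokine made by Treg and Th2 cells, rose 5.21-fold (adjusted p = 2.79e-04). Their adjusted p without the block was 0.513 and 0.0757. Smad3, which carries TGF-β signals to the nucleus, rose 3.23-fold (adjusted p = 0.00514) and E2f2, a cell cycle transcription factor, 2.16-fold (adjusted p = 0.00928). The deepest falls were in Il1a, the cytokine IL-1α (log2 fold change -1.50, SE 0.14, adjusted p = 0.00749), the chemokine Ccl1 (-1.27, SE 0.11) and Inhba, a subunit of activin A (-1.14, SE 0.12). S1pr3, a sphingosine 1-phosphate receptor (-1.08), the chemokine Ccl9 (-1.06) and the repressor Zbtb32 (-1.04) fell too. Nkg7 (-0.97), Cd70, the ligand of CD27 (-0.94), Tal2 (-0.92), Rgs2 (-0.91), Cxcl2 (-0.90) and Anxa3 (-0.89) were the rest of the 12 largest falls. Without replicate 2 the paired fit gave 74 genes, 8 of them lower, and without replicate 3 it gave 41, 0 of them lower in limma, where 794 fell at an unadjusted p under 0.05. Il1a had an adjusted p of 0.0766 and Inhba of 0.139 without replicate 3, while Cdh1 and Il10 passed in each case. Smad3 (0.0658) and E2f2 (0.0948) were also lost without replicate 3.

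Of 18 Th1 genes measured, 0 passed without the block and 5 fell when adjusted over the list alone, and with the block 6 fell and 0 rose. Nkg7, a protein of cytotoxic granules, fell by 0.97 on the log2 scale (SE 0.12, adjusted p = 0.0193) and Il18rap, a chain of the IL-18 receptor, by 0.73 (SE 0.09, adjusted p = 0.0244), both in the paired fit. Both calls were lost without pair 2 (adjusted p = 0.123 and 0.166) and without pair 3 (0.128 and 0.168). The list fell (adjusted p = 4.58e-04, adjusted p = 0.179 with an estimated correlation, adjusted p = 1.76e-06 in the paired fit, where adjusted p = 0.491 with an estimated correlation). In the Treg signature 0 of 27 genes passed without the block, and with it 1 rose, Il10, and 3 fell. These were Penk, the enkephalin precursor (-0.87, adjusted p = 0.00806), the activation marker Cd83 (-0.76, adjusted p = 0.0176) and the costimulatory receptor Icos (-0.51, adjusted p = 0.0418). Tnfrsf4, which encodes OX40, had a log2 fold change of -0.44 (adjusted p = 0.0752 in the paired fit). When adjusted over the list alone, 1 rose without the block, and 2 rose and 6 fell with it. The list had an adjusted p of 0.111 and fell in the paired fit (adjusted p = 0.0028, adjusted p = 0.491 with an estimated correlation).

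Of 33 cytokine genes 1 rose without the block, Il4, and with it 5 rose and 7 fell. Il10 and Il4 were among the rises and Ccl1, Cd70 and Il24 (-0.69) among the falls. Adjusted over the list alone, 3 rose and 3 fell without the block. The list's adjusted p was 0.63, and it fell in the paired fit (adjusted p = 0.0151, adjusted p = 0.491 with an estimated correlation). In the Th2 list 1 of 15 rose, Il4, and in the paired fit Il10 rose and Il24 and Il9 fell (list adjusted p = 0.63). In the follicular helper list 1 of 17 rose, Cxcr5, and in the paired fit 4 fell, Cd200, Pou2af1, Icos and Btla. This list had an adjusted p of 0.734 in camera, pointing up, and 0.726 in the paired fit, pointing down. It passed in fry (adjusted p = 0.0143, and 0.00116 in the paired fit). Of 19 chemokine receptors 2 rose, Cxcr5 and Cxcr4, and in the paired fit Cxcr6 fell (-0.83, adjusted p = 0.0322). The Cxcr6 call was lost without pair 2 (0.152) and without pair 3 (0.134). The chemokine receptor list had an adjusted p of 0.541 in camera and 0.0143 in fry (0.0690 in the paired fit). In the Th2, follicular helper and chemokine receptor lists the median was negative and the mean positive. Without the pairing camera pointed down in the first and last and up in the other. Adjusted over the list alone, 2 rose and 1 fell in the Th2 list, 1 rose and 2 fell in the follicular helper list and 2 rose and 1 fell among chemokine receptors.

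**Figure D3:**
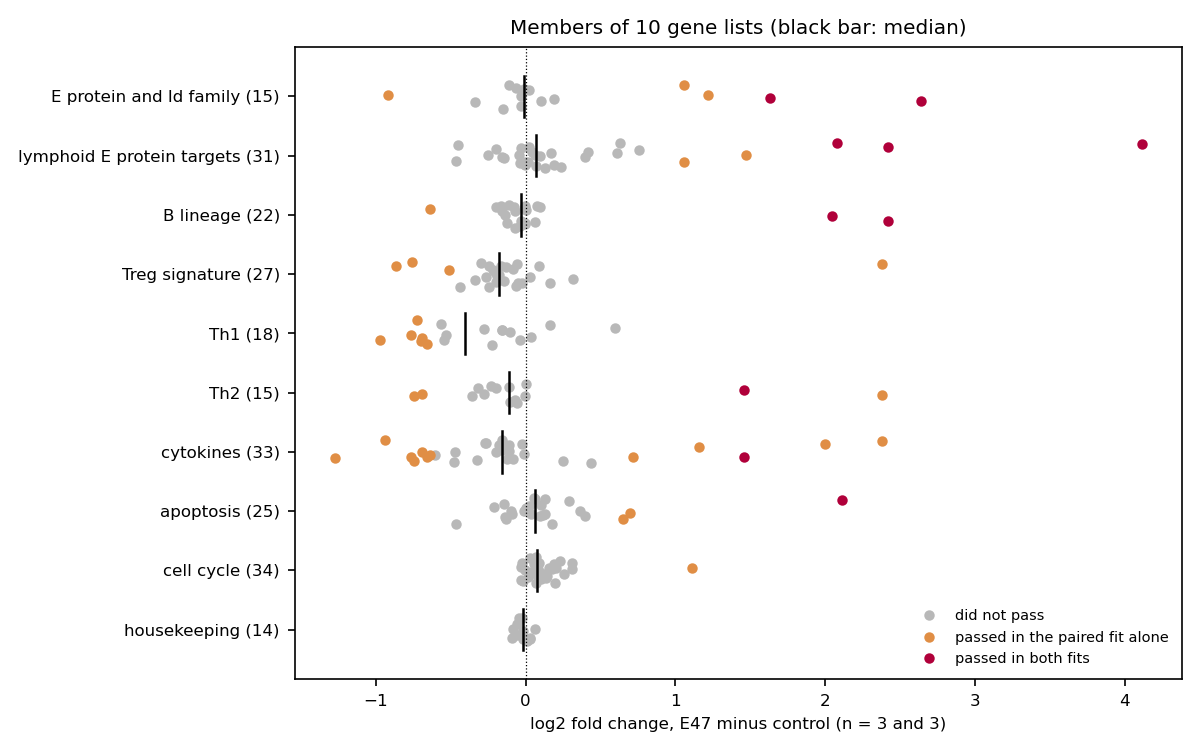
Log2 fold change, E47 minus control, of each measured member of 10 gene lists (number of members in brackets); colours mark the test passed and the black bar is the list median. The medians ran from -0.41 for Th1 genes to 0.08 for cell cycle genes, so the few large rises stood apart from their lists.

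The cell cycle list shifted up, with a median log2 fold change of 0.08, 29 of 34 members higher and 0 that passed (adjusted p = 2.42e-04, adjusted p = 0.843 with an estimated correlation). Its call was lost without E47 replicate 2 (adjusted p = 0.574) and without control replicate 3 (0.0537). The SOCS and JAK-STAT list (31 members, median 0.07), the integrated stress and unfolded protein response list (25, median 0.04), the cholesterol synthesis list (17, median 0.09) and the construct list (Thy1 0.82, Esr1 0.21 and Tcf3 -0.01) also shifted up, each at adjusted p = 0.0469. With an estimated correlation their adjusted p was 0.322, 0.843, 0.843 and 0.322. The cholesterol list was lost without control replicate 1 (adjusted p = 0.875), pointed down without E47 replicate 3 (0.856) and reached 1.79e-06 without E47 replicate 1. The SOCS and JAK-STAT call was kept in 4 of 17 alternative settings and lost whichever single array was left out (adjusted p up to 0.122, without E47 replicate 2). The stress and construct calls were each kept in 8 of 17. Their adjusted p reached 0.282 without E47 replicate 3 and 0.123 with genes brighter than the median alone. In the paired fit Socs3 and Pim2, a kinase induced by cytokines, rose in the SOCS and JAK-STAT list, E2f2 in the cell cycle list and Thy1 among the construct genes. No member of these lists passed over all genes without the pairing, and adjusted over the list alone Jak2, a cytokine receptor kinase (-0.58), Atf3, a stress-induced transcription factor (0.89), and Thy1 did. Median centring, quantile normalization and cyclic loess each left 4 of the 8 shifted lists. Of the other splits of the 6 arrays, 1 that kept both arrays of experiment 2 together also gave 8 lists. The rest that kept a pair together gave 7, 5, 4, 1 and 1, and the 3 that part every pair gave 1, 0 and 1.

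In the apoptosis list 1 of 25 rose, Bcl2l11 (1 rose and 1 fell adjusted over the list alone), and in the paired fit Pmaip1, which encodes the death-promoting protein Noxa (0.70, adjusted p = 0.0276), and Bid rose as well. The paired call of Pmaip1 was lost without pair 2 (adjusted p = 0.183) and without pair 3 (0.171). The list had an adjusted p of 0.0608, and rose in the paired fit (adjusted p = 0.0106, adjusted p = 0.491 with an estimated correlation). Another 3 lists shifted in the paired fit alone, and none did with an estimated correlation (adjusted p = 0.491, 0.617 and 0.491). The Th17 list shifted down (13 members, adjusted p = 0.0451) and the list of naive cells and migration up (19 members, adjusted p = 0.0456), although 0 members of either passed in either fit. The activation and immediate early list shifted down (34 members, adjusted p = 0.0104), with 0 members past the threshold without the pairing and 2 that fell adjusted over the list alone. Egr2 and Fosl2, both induced by T cell stimulation, were the 2 members that fell in the paired fit (-0.69 and -0.68), and both were lost without pair 2 (adjusted p = 0.107 and 0.170) and pair 3 (0.122 and 0.107). The other lists did not shift in either fit. Without the pairing their adjusted p was 0.541 for the TGF-β pathway, 0.753 for the T cell receptor complex, 0.725 for D-type cyclins and CDK inhibitors, 0.753 for Notch, 0.851 for interferon response, 0.586 for heat shock, 0.63 for glycolysis and hypoxia and 0.373 for the TNF receptor family. No member of these 8 lists passed without the pairing. In the paired fit Smad3 rose in the TGF-β pathway, Vegfa (0.94, adjusted p = 0.0377) in the hypoxia list, and the adaptors Sla (-0.58, adjusted p = 0.0294) and Trat1 (-0.54) fell in the T cell receptor list. Vegfa was lost without pair 2 (adjusted p = 0.194) and pair 3 (0.161), and Sla likewise (0.218 and 0.183). Adjusted over the list alone without the pairing, 3 rose and 1 fell in the TGF-β pathway, 1 rose and 2 fell in the T cell receptor list, 1 rose in the hypoxia list and 0 passed in the others. The median was negative and the mean positive in the TGF-β and hypoxia lists, and the reverse held for D-type cyclins. The 14 housekeeping genes had a median log2 fold change of -0.02 and 0 passed (list adjusted p = 0.952).

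Markers of other cells were read in the same arrays, since a CD4+Thy1.1+ sort may hold some. Of 11 B cell markers 1 rose, Ighm, and in the paired fit Fcrl1 fell (-0.75, adjusted p = 0.0271; 0.183 without pair 2 and 0.0714 without pair 3; list adjusted p = 0.753). Of 19 myeloid and dendritic markers and 12 markers of CD8, NK and γδ T cells 0 passed (list adjusted p = 0.0756 and 0.947), with Cd14 at -0.25, Itgax at -0.26, Cd8b1 at 0.51 and Prf1 at -0.22. Of 16 stromal, endothelial and erythroid markers 1 rose, Epcam, while Krt8 had a log2 fold change of 0.44 (SE 0.15; list adjusted p = 0.747).

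The 3 experiments also differed among themselves. Between them 582 genes differed, 246 by at least 2-fold between 2 experiments. Foxp3 was among them, with a mean log2 level over both groups of 8.00 in experiment 2 against 6.39 and 6.18 in experiments 1 and 3 (adjusted p = 0.00262). Gpr83, another gene of Treg cells, and Itga6, an integrin chain, were also higher in experiment 2, and Il9, a cytokine of Th9 cells, was lower (6.69 against 9.59 and 9.66). With 1 sample per group in each experiment, the E47 change has no test within a single experiment.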

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

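No test in this part was chosen after its result was seen. Of the probe sets without a single gene symbol here, which belong to no comparison of the report, 3 were higher in E47 than in control samples among 10092 tested beside all other probe sets in limma, and 0 were lower. The largest of these differences was 5.22-fold. In the paired fit 5 were higher. They are counted here as a signal in data not used in the gene tests, and their identity was not analysed here. None of the 64 control probe sets passed in either fit.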

How the results depend on the processing

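The paired fit and its own alternatives, reported as a result of their own, and the naming rule applied to it were chosen after the data were seen; the other alternatives were not. With the experiment as a block 208 genes changed (142 higher, 66 lower, 84 at least 2-fold) and 14 lists shifted; with a random block 92 changed (79 higher, 13 lower). All 45 unpaired calls were among both sets. Genes brighter than the median alone gave 29 changed (29 higher, 0 lower, with 219 lower at an unadjusted p under 0.05) and 26 at least 2-fold; dim risers such as Cxcr4 were not tested there. Lower genes numbered 4 with trend and robust variance, 2 with array weights and 0 with median centring, where 580 were lower at an unadjusted p under 0.05; the cause was not tested. Leaving out replicates gave 5 to 65 changed, 5 to 59 higher, 0 to 6 lower, 5 to 55 at least 2-fold and 5 to 14 lists. The count fell to 15 without control replicate 1, 23 without control replicate 3 and 17 without E47 replicate 3. It fell to 9 without replicate 1 and 5 without replicate 3, and the cause was not tested. Tests on fewer arrays detect less, so a call lost with arrays left out does not by itself show dependence on 1 experiment. Without replicate 2, however, 65 changed. Other settings left 40 to 47 genes, and all probe sets tested one by one gave 52.

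Lists shifted numbered 4 each with median centring, quantile normalization and cyclic loess, 5 with fry, 0 with an estimated correlation and 0 with an estimated correlation and the block, where 4 and 2 lists had an unadjusted p under 0.05. The E protein and Id family, the lymphoid E protein targets and Th1 passed in all 17 settings that kept the preset correlation. They passed in fry as well (adjusted p = 0.00426, 0.00558 and 0.0143). Their estimated correlations were -0.061, -0.017 and -0.026, below the preset 0.01, so correlated members were not what raised their p in camera. The cholesterol list turned direction in 1 of the 17 settings. Camera takes no block correlation, so lists under the random block were not run. The paired count was 362 with bright genes alone and 538 with trend and robust variance, and 41 to 288 with a pair left out (288 without replicate 1, 74 without replicate 2, 41 without replicate 3). Tcf3 changed sign with array weights (0.0015), median centring (0.0014) and the mean of its probe sets (0.0947), and ran from -0.0485 to 0.0457 across replicates left out. Foxp3 ran from -0.7436 (without E47 replicate 2) to 0.3978 (without control replicate 2) and was 0.1396 without E47 replicate 3, in fits that break a pair; it was lower in each of the 3 pairs. Sdha turned to 0.0481 with the mean of its probe sets. None of these passed a test. Of 86 named genes, 18 were called without the block, 12 of these in all 9 settings that kept every array, where the gene was tested. The block changed no other call than the 30 named genes that it added. Signal over background limits dim genes: 10 of the 45 calls had a control level below the median of all probe sets.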

Other observations

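The genes of this paragraph are single examples chosen after their values were seen. Klf4, a transcription factor of quiescence and pluripotency, rose by a log2 fold change of 1.56 without the pairing (adjusted p = 0.00623). Rasgrp3, an activator of Ras known from B cells, rose by 2.06 (adjusted p = 0.0318), and Grn, the progranulin gene, by 1.62 (adjusted p = 0.00163). In the paired fit Ikzf3, the lymphoid factor Aiolos, rose by 1.09 (adjusted p = 0.00581), Bcl3, a partner of NF-κB, by 0.90 (adjusted p = 0.0164), and Sik1, a kinase, by 0.86 (adjusted p = 0.0488). Rgs1, a relative of Rgs2, fell by 0.61 on the log2 scale (adjusted p = 0.0409) and Ptgs2, an enzyme of prostaglandin synthesis, by 0.87 (adjusted p = 0.0245).

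All tests below were chosen after the result was seen, except the counts over other splits, the repeat after cyclic loess and the comparison of experiments 1 and 3. The genes changed (45), higher (44), lower (1) and changed at least 2-fold (40) each had 1 of 10 splits of the 6 arrays into 3 and 3 with a count as large, the real one, and the highest other count was 0 in limma. At an unadjusted p under 0.05 the other splits gave 185 to 1850 genes against 1209 for the real split. The paired count of 208 was the 1 largest of the 4 splits that part every pair, the others giving 0, with 209 to 1256 genes at an unadjusted p under 0.05. For the 8 lists, 2 of 10 splits gave as many, and the other one set control replicates 1 and 2 and E47 replicate 2 against the rest, so that both arrays of experiment 2 stood together. The remaining splits that part every pair gave 0 or 1 list, and those that keep a pair together gave 7, 5, 4, 1 and 1. Neither 10 nor 4 splits are enough for a share under 0.05.

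Genes known from other lineages (Cxcr5, Ighm and Spib of B cells, Epcam and, in the paired fit, Cdh1 of epithelium, Plaur and Grn of myeloid cells) rose with E47. They are not confined to those lineages, and Cxcr5 is also in the follicular helper list. In control arrays Ighm lay at percentile 92.7 of all probe sets and Plaur at 78.5, while Cxcr5 lay at 40.5 and Cdh1 at 28.4. Cells of these other lineages in the E47 samples would bring their other abundant transcripts, and a CD4+Thy1.1+ sort should remove them. The median log2 fold change was -0.127 over 11 B cell markers (quartile range 0.147), -0.0815 over 19 myeloid markers (0.158) and 0.00319 over 19 epithelial markers (0.398, Epcam and Cdh1 included; Krt18 0.11, Krt19 -0.13, Cldn7 -0.21, and, highest of the rest, Muc1 0.66, Cldn4 0.48 and Krt8 0.44), against smallest rises to explain of 2.05, 1.62 and 3.04. This argues against all 3, by a rule rewritten after the values were seen. An explanation that stays is that E47 acts on these genes in the T cells, and it was not tested apart from the group comparison.

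Thy1 was higher in E47 arrays by 0.82 on the log2 scale. Array-wide scaling would move stable genes alike, and the housekeeping list had a median of -0.0159 with a quartile range of 0.0689. RMA equalises the distributions of the arrays beforehand, so a median near this was largely fixed and cannot decide on scaling. More vector message in the E47 cells would also raise Esr1, whose brightest probe set had 0.208 (SE 0.13), too uncertain to tell, and the probe sets may not cover the ER part in the virus. A change of the cells' own Thy1 stays open.

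E47 changes ran along the difference between experiments. Of 208 genes changed in the paired fit, 76 were among the 582 that differed between experiments, against 6.65 for independent lists, and 84.2% of the 76 moved with E47 in the direction in which experiment 2 differed from the others. Cdh1, Gfi1 and Socs3 were higher in both, and Il9 and S1pr3 lower. Tshb, Tspan2 and Il10 went the other way, higher with E47 and lower in experiment 2, and Ccl1 was lower with E47 and higher in experiment 2. Across the 582 genes, which are not independent replicates, r was 0.37 and 0.375 after cyclic loess. The value thus did not depend on the brightness-dependent differences that cyclic loess removes. RMA had equalised the arrays beforehand, so little change was likely, and the repeat does not decide on scaling in general. With experiment 1 minus experiment 3, r was 0.0791. Swapping the members of a pair gave r from -0.32 to 0.34 with the difference of experiment 2. Values of this size arise by alignment alone, so 0.0791 cannot decide on a general drift between experiments. Low spread of the same genes in both tests could account for the overlap, and chance alignment for the shared direction, since called genes move alike in all pairs and swapping the members of a pair still gave r up to 0.34; this cannot be told apart here. The rule for the low-spread test was rewritten after its earlier form proved unable to fail.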
